A study of Mus musculus with 18 samples.

How the data were processed

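Lung RNA was measured in 18 samples on single-colour oligonucleotide arrays, with 3 arrays in each of 6 groups. The groups were untreated and irradiated mice of the inbred strains A/J, C57BL/6J (written C57BL6/J in the labels) and C3H/HeJ. Per the labels' protocols, mice received 18 Gy to the whole thorax from a caesium source at 8 weeks of age, with a lead shield that cut the beam to 3% elsewhere, and were sacrificed when moribund. The right lung was homogenized and its total RNA was labelled with biotin. Each sample was placed in its group by its title, strain and treatment labels.

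The deposited values are 1 linear signal intensity for each of 45101 probe sets and each array, and the submitters' processing notes name MAS5, without a version. MAS5 signals are usually scaled to a common target, and the analysis plan, written before the data were examined, therefore used the deposited intensities with no further scaling. The values did not bear that out: the mean signal after 2% was trimmed at each end ranged from 46.5 to 176 between arrays, and the median signal from 14.8 to 39.7. The main setting was therefore changed to quantile normalization of log2(signal + 7), where 7 is the 25th percentile of all deposited values, rounded. The planned setting without scaling was kept as an alternative, and so was centring each array on its median. Fold changes are on the log2(signal + 7) scale, which understates the change of dim genes. Background handling, scanner settings and the date of hybridization were not given in the sources used here. Precision is limited by the number of arrays. Control hybridization signals and the ratios of 5' to 3' probe sets of actin and Gapdh were read from the 64 control probe sets, which were left out of all tests.

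A probe set was kept if its normalized value lay above the overall median in at least 3 of the 18 arrays, which left 25746. Gene names came from the platform annotation, updated through gene identifiers. Of its 35890 probe sets, 34958 named 1 gene and 932 named several. A further 9160 probe sets of the table had no row in that annotation and stay unnamed here. A gene with several kept probe sets that named it alone was represented by the one with the highest mean, giving 12412 genes. Where another probe set of a named gene was called in the opposite direction, this is said beside the gene.

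Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on all 18 arrays, as a model of 6 group means with 1 shared estimate of the spread and 12 residual degrees of freedom. The comparisons were irradiated against control in each strain, the 3 differences of these effects between strains, and the 3 differences between untreated strains. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All adjusted p-values of genes below come from this limma fit, and errors of fold changes are standard errors. Moribund mice of a strain are separate animals per the labels, while for the controls the labels say only that 3 samples came from control mice. If controls shared animals, the p-values would measure technical spread there.

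Gene lists for lung cell types, matrix, inflammation, DNA damage and neighbouring tissues, 36 in all, were fixed before the data were examined. The 35 with at least 4 measured genes were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, with adjustment over the lists of a comparison. The thymus list had 3 measured genes and was not tested. camera with an estimated correlation was an alternative. fry, which tests whether the genes of a list move on balance one way, was run beside it. Its results are given below only for some lists in A/J. Every p given for a list is camera's adjusted p unless said otherwise. Counts of list members that rose or fell are given over all genes tested and also adjusted over the list alone.

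Genes were named by a rule fixed before the data were examined. For each treatment effect it takes the 8 highest and 8 lowest fold changes among called genes whose treated and control arrays do not overlap. It takes up to 4 called members of each list described, the 6 highest and 6 lowest called genes of each difference of effects, and the 5 highest and 5 lowest of each untreated strain pair. Cdkn1a, Col1a1, Col3a1, Fn1, Timp1, Tgfb1, Mmp12, Sftpc, Scgb1a1, S100a8, Cpa3, Pecam1 and 4 sex-linked genes are given whatever their result, except that no change is given for Sftpc and Scgb1a1, whose high ranks limit it under quantile normalization. Spp1 and Ddx3y were on that list too and are not analysed here.

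The fit was tested on simulated arrays with 12085 genes, of which 11869 were unchanged and the others had known changes. Far fewer genes changed there than were called in the real A/J arrays, so the shares of false calls need not carry over. For the effect in A/J, 33.3% of genes changed by 0.5 on the log2 scale were called in the right direction, 79.7% at 1 and 98.4% at 2, and 2.8% of the calls were unchanged genes. For the difference between C57BL/6J and A/J the shares were 11.1%, 51.6% and 90.2%, with 3.96% false calls. A list shifted by 0.5 was called, and 0 of 34 unshifted lists were. This does not give the rate of false list calls in the real arrays. In A/J 15 real lists were called with the preset correlation and 0 with an estimated one.

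Alternatives fixed before the data were examined were no scaling, median centring, an offset of 1, no filter, a stricter filter (9 arrays), all probe sets as units, a fit on only the groups compared, a variance trend with a robust prior, the replicate number as a block, and leaving out each array in turn. Leaving out 3 arrays with high signals of squamous keratins was added after seeing the data. Replicates of a group correlated at 0.944 to 0.986, and no pair of arrays shared more than 1.04% of identical values, so each array counted as 1 replicate.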

Results

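Lung RNA was profiled in 3 inbred mouse strains that differ in the lung disease they develop after thoracic irradiation. C57BL/6J is known for a fibrosing response, and A/J and C3H/HeJ mainly for alveolitis, an inflammation of the air sacs. Each strain had 3 samples from untreated mice and 3 from mice that became moribund after 18 Gy to the whole thorax, so that the arrays ask which genes differ in the lung at that stage and whether strains differ in it. Controls of each strain were 15 to 26 weeks old. Irradiated mice were 30 to 32 weeks old in A/J, 28 to 30 in C57BL/6J and 20 to 22 in C3H/HeJ, which puts them 22 to 24, 20 to 22 and 12 to 14 weeks after exposure. Time since exposure and moribund state therefore go together with irradiation in each strain, and so does age in A/J and C57BL/6J, while irradiated C3H/HeJ mice lay within the age range of the controls. The fits cannot separate these.

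Signals differed in overall brightness between arrays, from a trimmed mean of 46.5 in the dimmest untreated C3H/HeJ array to 176 in the brightest irradiated A/J array. Without scaling, the median log2 fold change of all genes was 0.56 in A/J, 0.06 in C57BL/6J and 0.61 in C3H/HeJ, and after median centring it was 0.33, 0.01 and 0.24. Fold changes below come from quantile-normalized signals and are relative to this shift. The ratio of 5' to 3' actin signal, a measure of how intact the labelled RNA was, was 0.497 ± 0.074 (SD, n = 3) in irradiated A/J lung and 0.735 ± 0.006 in untreated A/J lung. In the other groups its mean lay between 0.709 and 0.745. The same ratio for Gapdh was 0.734 ± 0.389 in irradiated A/J lung, with array 1 at 0.294, against 1.24 ± 0.0873 in untreated A/J lung and means of 1.16 to 1.20 in the other groups. Low ratios thus go together with irradiation in A/J, and the fits cannot separate RNA quality from irradiation there.

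In irradiated A/J lung the largest increases were in genes of mast cells, the granule-rich cells of allergic inflammation. Cpa3, a mast cell carboxypeptidase, rose by 3.84 ± 0.47 on the log2 scale (14.3-fold, 3 arrays against 3, adjusted p = 4.15e-05), and the tryptases and chymases Tpsb2, Mcpt4, Cma1 and Tpsab1 rose by 3.48, 3.32, 3.29 and 3.13. Dbp, an output gene of the circadian clock, rose by 3.54 ± 0.20, the immunoglobulin gene Ighg3 by 3.02 ± 0.72 and the chemokine Ccl8 by 2.93 ± 0.42. The largest decreases were in Acoxl (−3.78 ± 0.45), the fatty acid binding protein Fabp1 (−3.41 ± 0.48), the MHC class II gene H2-Ea (−3.13 ± 0.30), the prostaglandin-degrading enzyme Hpgd (−3.03 ± 0.40), Gprin3 (−2.95 ± 0.25), Grtp1 (−2.72 ± 0.33), Sfpq (−2.62 ± 0.22) and Rnf144a (−2.54 ± 0.19). These 16 calls held under every alternative run. In all, 2986 of 12412 genes were called in A/J, 1875 higher and 1111 lower, and 2616 were called without irradiated array 1, which had the lowest 5' to 3' ratios. The actin ratio was 0.413, 0.551 and 0.528 in the 3 irradiated A/J arrays, each below the untreated A/J mean of 0.735. Neither leaving out array 1 nor any other alternative run can therefore separate RNA quality from irradiation in A/J. The split was 2312 higher and 144 lower without scaling, and 4162 and 536 after median centring.

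Matrix genes rose together in A/J. Of 38 measured collagen and matrix genes, 27 rose and 2 fell (29 and 2 adjusted over the list alone, adjusted p = 1.9e-09). Tnc, the wound matrix protein tenascin C, rose by 2.52 ± 0.36, Col5a2 by 2.26 ± 0.26, Col18a1 by 2.24 ± 0.19 and Col1a1, the main chain of fibrillar collagen, by 2.23 ± 0.23. Among matrix proteases and their inhibitors 18 of 26 rose and 0 fell (20 and 1 adjusted over the list alone, adjusted p = 5.27e-08), led by the inhibitor Timp1 (2.93 ± 0.35), the macrophage elastase Mmp12 (2.43 ± 0.50) and Ctsk (2.36 ± 0.42). Among complement and acute-phase genes 19 of 23 rose (19 adjusted over the list alone, adjusted p = 2.31e-09), among them Serpina3n (2.79 ± 0.25), Saa3 (2.36 ± 0.33) and Lcn2 (2.34 ± 0.24). Macrophage markers rose in 19 of 32 cases and fell in 1 (20 and 1 adjusted over the list alone, adjusted p = 3.66e-06), with Retnla at 2.80 ± 0.23 and Trem2 at 2.21 ± 0.48. Of 17 glucocorticoid-responsive genes 12 rose (12 adjusted over the list alone, adjusted p = 2.44e-07), including Per1 (2.62 ± 0.16), the metallothionein Mt2 (2.59 ± 0.29) and Fkbp5 (2.36 ± 0.22). Per1, which is also on the clock list, had untreated means of 5.80, 7.59 and 5.95 in A/J, C57BL/6J and C3H/HeJ and irradiated means of 8.42, 7.5 and 7.24. Untreated means of Fkbp5 were 5.67, 7.19 and 6.14, and irradiated means were 8.03, 8.37 and 8.15. Mast cell markers rose in 7 of 11 cases and fell in 1 (7 and 2 adjusted over the list alone, adjusted p = 0.00273). The receptor gene Kit, which mast cells and other cells carry, went the other way (−1.55, −2.16 and −2.06 in A/J, C57BL/6J and C3H/HeJ). With an estimated correlation none of these 6 list calls held. The adjusted p was then 0.071 for matrix, 0.162 for proteases, 0.162 for complement, 0.576 for macrophages, 0.071 for glucocorticoid response and 0.292 for mast cells. With fry the adjusted p of these 6 lists ran from 2.35e-07 (glucocorticoid response) to 0.00968 (macrophages). fry does not compare a list with other genes, so it answers a different question.

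Targets of p53, the DNA damage regulator, rose in 10 of 27 cases and fell in 1 in A/J (11 and 1 adjusted over the list alone, adjusted p = 0.00596, 0.26 as adjusted p with an estimated correlation). They included the cell cycle inhibitor Cdkn1a (1.77 ± 0.28) and Zmat3 (1.59 ± 0.13). Of 22 genes of T and NK cells 8 fell and 0 rose (8 and 1 adjusted over the list alone, adjusted p = 0.000488, adjusted p = 0.292 with an estimated correlation), with the granule protease Gzma at −2.13 ± 0.41 and the pore-forming protein Prf1 at −1.46 ± 0.22. Endothelial genes fell in 15 of 35 cases and rose in 7 (16 and 7 adjusted over the list alone, adjusted p = 0.00038, adjusted p = 0.285 with an estimated correlation). The angiopoietin receptor Tek fell by 2.14 ± 0.18, Tmem100 by 2.52 ± 0.29 and the receptor component Calcrl by 1.96 ± 0.14. The median of the endothelial list was −0.38 and turned to 0.19 without scaling, where it lay at −0.36 relative to the median of all genes. Airway club and secretory cell genes fell in 5 of 21 cases and rose in 2 (5 and 2 adjusted over the list alone, adjusted p = 0.045, 0.655 as adjusted p with an estimated correlation). That call was lost without scaling (adjusted p = 0.435), after median centring (0.106) and without the 3 arrays named below for squamous keratins (0.203), and its median turned from −0.10 to 0.31 and 0.08 under those scalings.

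In irradiated C57BL/6J lung antibody genes led the increases. Ighg3, Iglv1, Igkv9-120 and Igkv6-14 rose by 3.30 ± 0.72, 3.17 ± 0.46, 3.07 ± 0.51 and 2.79 ± 0.37, and Jchain, which links secreted antibodies, by 2.58 ± 0.40. Cdkn1a rose by 2.57 ± 0.28 (5.94-fold, 3 arrays against 3, adjusted p = 0.000109), the macrophage glycoprotein Gpnmb by 2.36 ± 0.45 and the neutrophil surface gene Cd177 by 2.29 ± 0.24. The largest decreases were in Lce3c (−3.22 ± 0.85), the apelin receptor Aplnr (−2.82 ± 0.37), the squamous keratin Krt78 (−2.76 ± 0.56), Lce3b (−2.58 ± 0.70), Ankrd63 (−2.57 ± 0.23), Sox11 (−2.42 ± 0.27), the atrial peptide gene Nppa (−2.32 ± 0.64) and the receptor gene Kit (−2.16 ± 0.25). In all, 664 genes were called, 371 higher and 293 lower. The count was 79 in a fit on only the groups compared, 220 without scaling, 342 after median centring and 324 with the replicate block. Leaving out C57BL/6J irradiated array 1 gave 219, irradiated array 2 gave 416, control array 1 gave 221 and control array 3 gave 290.

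Squamous keratin signals stood apart in C57BL/6J control arrays 1 and 3. There Krt4, a keratin of the oesophagus and other squamous linings, had normalized log2 signals of 11.5 and 11.7, against 4.43 in C57BL/6J control 2 and 3.06 to 4.59 in irradiated C57BL/6J lung. A/J irradiated array 3 was high as well, at 10.9. The skeletal muscle list had its highest means in the same 3 arrays, 8.16, 7.96 and 8.14, against at most 6.44 elsewhere. Without these 3 arrays, a choice made after seeing the data that leaves 1 C57BL/6J control assumed to vary like the other groups, 32 genes were called in C57BL/6J. The calls of Cdkn1a, Cd177, Ankrd63, Sox11 and Kit held there, and the other 11 of the 16 named calls did not. Of these 11, Ighg3 (3.09 ± 0.93), Iglv1 (2.75 ± 0.68), Igkv9-120 (2.70 ± 0.67), Igkv6-14 (2.41 ± 0.52), Gpnmb (1.93 ± 0.63) and Aplnr (−2.64 ± 0.54) stayed within 1.5 times of their log2 fold changes over all arrays, with larger standard errors. Jchain (1.56 ± 0.48), Krt78 (−1.34 ± 0.64), Nppa (−1.08 ± 0.85), Lce3b (−0.87 ± 0.52) and Lce3c (−0.56 ± 0.39) shrank by more than that. With 1 array left out, Ighg3 was lost without irradiated 1, irradiated 2, control 1 or control 3, with fold changes from 2.96 to 3.92, and Krt78 without irradiated 1, control 1 or control 3, from −3.46 to −2.37. Nppa was lost without irradiated 1, irradiated 2, control 1 or control 3, from −2.94 to −1.80. Lce3c and Lce3b were lost without any of the arrays but control 2, from −4.55 to −2.53 and from −3.44 to −2.06.

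Complement and p53 genes made up the firmest groups in C57BL/6J. Of 23 complement and acute-phase genes 16 rose and 0 fell (21 and 0 adjusted over the list alone, adjusted p = 3.52e-19, adjusted p = 0.0432 with an estimated correlation), such as Saa3 (2.01 ± 0.33), the fibrinogen chain Fgg (1.94 ± 0.36) and C1qc (1.60 ± 0.29). Of 27 p53 targets 11 rose and 0 fell (11 and 1 adjusted over the list alone, adjusted p = 2.77e-10, adjusted p = 0.0158 with an estimated correlation), with Zmat3 at 1.40 ± 0.13 beside Cdkn1a. Genes of B and plasma cells rose in 7 of 16 cases (8 adjusted over the list alone, adjusted p = 3.02e-09, adjusted p = 0.111 with an estimated correlation), with Igha at 2.13 ± 0.23. Interferon-responsive genes rose in 11 of 30 cases (14, with 2 lower, adjusted over the list alone, adjusted p = 8.93e-08, adjusted p = 0.233 with an estimated correlation), with Cxcl9 at 2.18 ± 0.39 and Ifit1 at 1.27 ± 0.20. Macrophage markers rose in 9 of 32 cases (17 adjusted over the list alone, adjusted p = 1.7e-10, adjusted p = 0.293 with an estimated correlation), with Retnla at 1.69 ± 0.23. Collagen and matrix genes rose in 6 of 38 cases (15 adjusted over the list alone, adjusted p = 0.000235, adjusted p = 0.233 with an estimated correlation). The crosslinking enzyme Lox rose by 1.62 ± 0.30 and fibronectin, Fn1, by 0.78 ± 0.15, and the Fn1 call was lost without scaling. Without the 3 arrays high in squamous keratins the calls of Zmat3 (1.66 ± 0.18) and Igha (1.72 ± 0.32) held. Those of Saa3 (1.63 ± 0.47), C1qc (1.42 ± 0.38), Retnla (1.35 ± 0.33), Fn1 (0.91 ± 0.23) and Ifit1 (0.90 ± 0.27) were lost with larger standard errors and log2 fold changes within 1.5 times of those over all arrays. The calls of Lox (1.07 ± 0.38), Cxcl9 (0.93 ± 0.29) and Fgg (0.75 ± 0.24) were lost with changes that shrank by more than that.

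Endothelial genes fell in 10 of 35 cases in C57BL/6J and rose in 1 (14 and 2 adjusted over the list alone, adjusted p = 5.36e-07, adjusted p = 0.111 with an estimated correlation). Bmp6 fell by 2.06 ± 0.19 and Tek by 1.68 ± 0.18. Muscle lists were also lower in this strain. Cardiac muscle genes fell in 3 of 15 cases (6 adjusted over the list alone, adjusted p = 0.000122, adjusted p = 0.349 with an estimated correlation), smooth muscle and myofibroblast genes fell in 2 of 16 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.00125, adjusted p = 0.349 with an estimated correlation), and the skeletal muscle list had 0 of 10 called members (0 adjusted over the list alone, adjusted p = 0.000467, adjusted p = 0.352 with an estimated correlation). Without the 3 arrays high in squamous keratins none of these 3 lists was called, with adjusted p of 0.528, 0.291 and 0.382, and the skeletal muscle list then pointed upward. The cardiac genes Sln and Myh7 went from −1.15 ± 0.31 and −0.71 ± 0.20 to −0.52 ± 0.39 and −0.33 ± 0.27. The smooth muscle genes Acta2 and Myl9 lost their calls but kept about their size, from −0.52 ± 0.14 and −0.50 ± 0.13 to −0.42 ± 0.21 and −0.46 ± 0.21. C57BL/6J controls 1, 2 and 3 had signals of 10.78, 10.59 and 10.68 for Acta2 and 10.17, 10.06 and 10.07 for Myl9. The cardiac list was also lower in C3H/HeJ, which had no array high in squamous keratins (7 of 15 fell, 9 adjusted over the list alone, adjusted p = 0.000171, adjusted p = 0.331 with an estimated correlation).

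In irradiated C3H/HeJ lung inflammatory signals and mast cell proteases led. The acute-phase gene Saa3 rose by 4.71 ± 0.33 (26.1-fold, 3 arrays against 3, adjusted p = 5.4e-07), the cytokine Il6 by 4.38 ± 0.41, Timp1 by 4.20 ± 0.35 and Ccl8 by 3.46 ± 0.42. The mast cell genes Tpsb2, Cpa3 and Mcpt4 rose by 4.16 ± 0.34, 3.84 ± 0.47 and 3.43 ± 0.48, and the adhesion molecule Chl1 by 3.29 ± 0.35. The largest decreases were in Acoxl (−3.28 ± 0.45), Tek (−2.74 ± 0.18), Rnf144a (−2.71 ± 0.19), Bmp6 (−2.71 ± 0.19), Hpgd (−2.62 ± 0.40), the GLP-1 receptor gene Glp1r (−2.60 ± 0.29), Hpcal4 (−2.55 ± 0.32) and Fabp1 (−2.55 ± 0.48). These 16 calls held under every alternative run. In all, 2915 genes were called, 1594 higher and 1321 lower. The split was 3195 higher and 71 lower without scaling, and 3015 and 461 after median centring. Array 3 of this group lay between C3H/HeJ and A/J at strain-marker probe sets, and without it 2178 genes were called.

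In C3H/HeJ, cell division and inflammation genes rose together with matrix genes, and 9 list calls held with an estimated correlation, each at an adjusted p of 0.039. Of 31 cell cycle genes 25 rose and 1 fell (27 and 1 adjusted over the list alone, adjusted p = 6.75e-12), with the proliferation marker Mki67 at 1.46 ± 0.25 and Ccnb2 at 1.38 ± 0.20. Chemokines and cytokines rose in 24 of 35 cases and fell in 2 (26 and 2 adjusted over the list alone, adjusted p = 2.05e-10), with Ccl2 at 2.76 ± 0.44 and Ccl24 at 2.70 ± 0.39. Complement and acute-phase genes rose in 21 of 23 cases (21 adjusted over the list alone, adjusted p = 3.76e-15), with Serpina3n at 3.07 ± 0.25 and Lcn2 at 2.82 ± 0.24. Collagen and matrix genes rose in 25 of 38 cases and fell in 1 (27 and 1 adjusted over the list alone, adjusted p = 2.05e-10), with Tnc at 2.78 ± 0.36, Col5a2 at 2.13 ± 0.26 and Thbs1 at 2.06 ± 0.36. Matrix proteases and inhibitors rose in 18 of 26 cases (22, with 1 lower, adjusted over the list alone, adjusted p = 3.14e-11), with Mmp12 at 3.17 ± 0.50, Adamts4 at 2.66 ± 0.33 and Mmp3 at 2.61 ± 0.23. Glucocorticoid-responsive genes rose in 11 of 17 cases (11, with 1 lower, adjusted over the list alone, adjusted p = 2.65e-07), with Mt2 at 2.85 ± 0.29 and Fkbp5 at 2.01 ± 0.22. Genes of dendritic cells and MHC class II rose in 12 of 19 cases (14 adjusted over the list alone, adjusted p = 3e-07), with Ccl17 at 2.69 ± 0.39 and Itgae at 1.88 ± 0.23. Neutrophil genes rose in 8 of 17 cases (11 adjusted over the list alone, adjusted p = 0.000171), with Mmp8 at 2.36 ± 0.21 and Il1r2 at 1.42 ± 0.28, and hypoxia and glycolysis genes in 8 of 23 (10 adjusted over the list alone, adjusted p = 0.00067), with Ankrd37 at 1.77 ± 0.28 and Ldha at 0.93 ± 0.16.

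Endothelial genes fell in 21 of 35 cases in C3H/HeJ and rose in 5 (22 and 5 adjusted over the list alone, adjusted p = 3.25e-07, adjusted p = 0.0541 with an estimated correlation). The phosphatase Ptprb fell by 2.30 ± 0.15 and Tmem100 by 2.20 ± 0.29. Macrophage markers rose in 21 of 32 cases and fell in 1 (23 and 1 adjusted over the list alone, adjusted p = 9.29e-10, adjusted p = 0.274 with an estimated correlation), with Retnla at 2.85 ± 0.23 and Trem2 at 2.70 ± 0.48. Mast cell genes rose in 8 of 11 cases and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.000701, adjusted p = 0.162 with an estimated correlation). Targets of p53 rose in 10 of 27 cases and fell in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.00067, adjusted p = 0.0672 with an estimated correlation), with Cdkn1a at 2.29 ± 0.28 and Eda2r at 1.72 ± 0.21. Genes of xenobiotic metabolism fell in 11 of 25 cases and 0 rose (12 and 1 adjusted over the list alone, adjusted p = 0.000184, adjusted p = 0.104 with an estimated correlation), led by Cyp1a1 (−2.04 ± 0.41) and Fmo1 (−1.69 ± 0.18). The median of that list was −0.28 and turned to 0.43 without scaling and 0.06 after median centring, in both cases below the median of all genes.

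**Figure D1:**
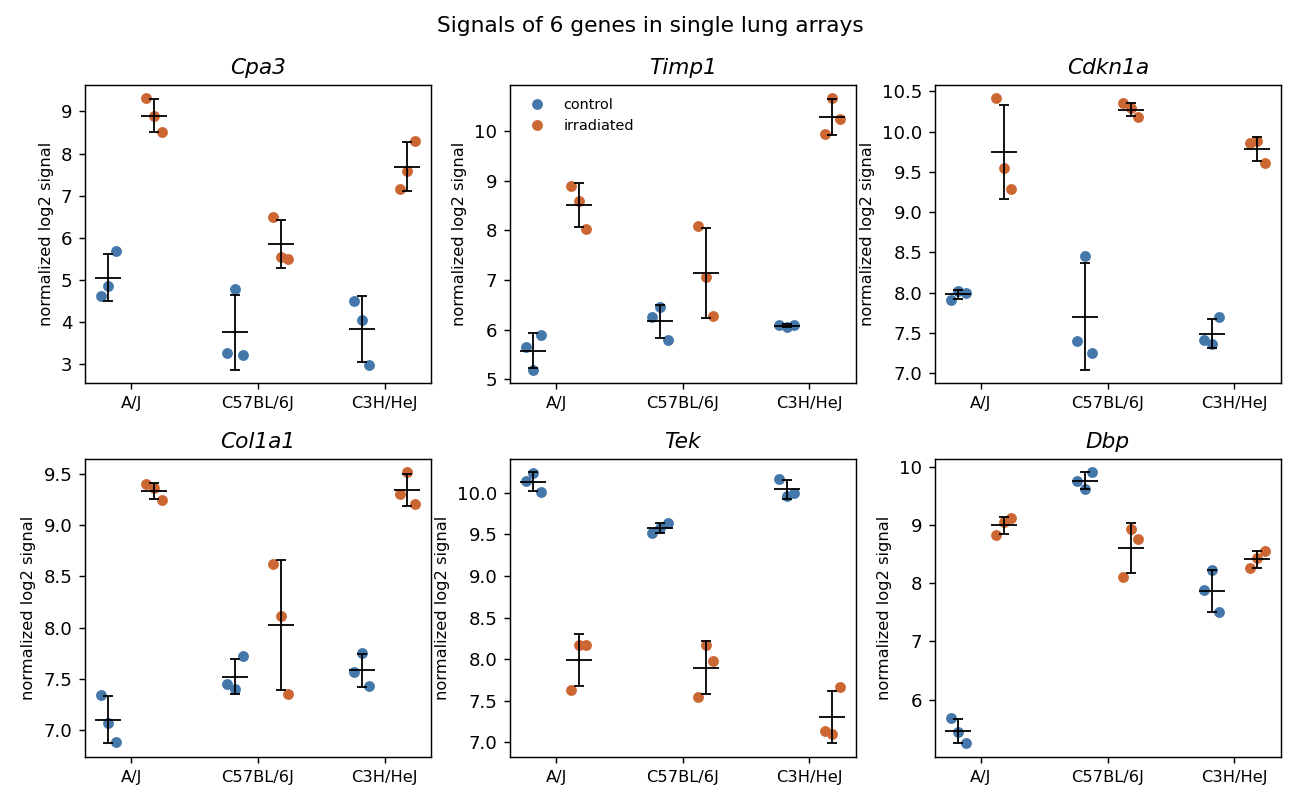
Normalized log2 signals of 6 genes in each of the 18 arrays, by strain on the horizontal axis, with untreated arrays in blue and irradiated arrays in orange; black bars are the group mean ± SD (n = 3). Cpa3, Timp1, Cdkn1a and Col1a1 are shown beside Tek, which fell by 2.14, 1.68 and 2.74 in A/J, C57BL/6J and C3H/HeJ, and Dbp, whose untreated means were 5.46, 9.76 and 7.87.

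**Figure D2:**
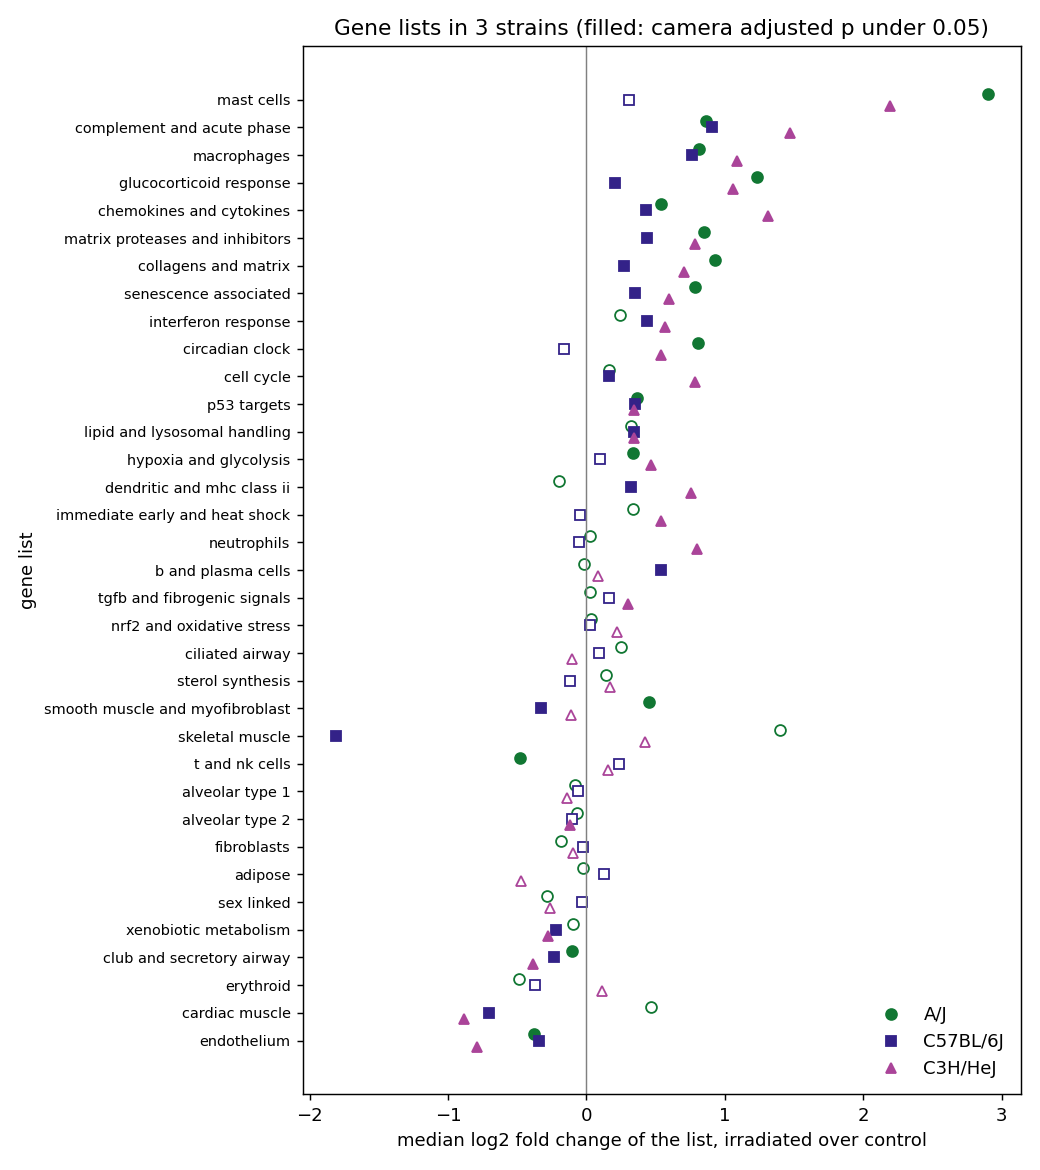
Median log2 fold change, irradiated over control, of 35 gene lists (vertical axis) in A/J (circles), C57BL/6J (squares) and C3H/HeJ (triangles), with filled symbols where camera's adjusted p was under 0.05. The complement and acute-phase list was called in all 3 strains, with medians of 0.86, 0.91 and 1.47, a call that was lost in A/J with an estimated correlation (adjusted p = 0.162), and the direction of lists with medians near 0 depends on the scaling.

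Across strains, 202 genes were higher and 120 were lower in all 3, where independent lists of these lengths would share 7.2 and 2.79. Each strain was compared with its own controls, so that no control array enters 2 of these comparisons. The 3 tests do share 1 estimate of the spread for each gene, which favours the same genes in each. The counts for independent lists are therefore a low reference. A/J and C3H/HeJ shared 851 higher and 539 lower genes (independent lists, 241 and 118), and 21 genes were called in opposite directions. C57BL/6J shared 245 higher and 131 lower genes with A/J (56 and 26.2 for independent lists) and 259 and 188 with C3H/HeJ (47.6 and 31.2). Genes higher in all 3 included Cpa3, Ccl8, Saa3, Cdkn1a and Gpr176, the last of these chosen after its values were seen (2.28, 1.98 and 2.39 in A/J, C57BL/6J and C3H/HeJ). Cpa3 rose by 2.09 ± 0.47 in C57BL/6J, a call lost without irradiated array 1, control array 1 or control array 3 of that strain (1.77 to 2.60 without 1 array) and without the 3 arrays high in squamous keratins (1.07 ± 0.59). Ccl8 signals in C57BL/6J were 9.546, 8.825 and 8.39 in irradiated arrays 1, 2 and 3 and 6.569, 7.22 and 6.299 in controls 1, 2 and 3. The rise of Ccl8 was thus smallest against control 2, the control not high in squamous keratins.

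Genes fixed in advance followed several courses. Col3a1 rose by 1.15 ± 0.18 in A/J and 1.29 ± 0.18 in C3H/HeJ. In C57BL/6J it rose by 0.66 ± 0.18 (adjusted p = 0.0477), and this call was lost without any of the 6 arrays but irradiated 3 (0.42 to 0.94) and without the 3 arrays high in squamous keratins (0.79 ± 0.28). Fn1 rose by 1.18 ± 0.15 in A/J and 1.38 ± 0.15 in C3H/HeJ. Col1a1 rose by 1.76 ± 0.23 in C3H/HeJ, while in C57BL/6J its change of 0.50 ± 0.23 (adjusted p = 0.228) did not pass, nor did Timp1 (0.98 ± 0.35, adjusted p = 0.123) or Mmp12 (1.72 ± 0.50, adjusted p = 0.0566). Tgfb1 passed in no strain (−0.31, 0.32 and 0.50 in A/J, C57BL/6J and C3H/HeJ). S100a8, a neutrophil gene, was −0.79 ± 0.27 in A/J (adjusted p = 0.0435) and 0.79 ± 0.27 in C3H/HeJ (adjusted p = 0.0437). The A/J call was lost without any of the A/J controls or irradiated array 3, with values from −1.06 to −0.35, and the C3H/HeJ call without any of its 6 arrays, with values from 0.68 to 0.88. S100a8 in C57BL/6J was −0.11 and did not pass. Pecam1, an endothelial surface gene, fell by 0.56 ± 0.15 in C3H/HeJ (adjusted p = 0.0138), a call lost without control array 1 and turned to 0.19 without scaling, and was −0.32 and 0.00 in A/J and C57BL/6J without passing. No change is given for the surfactant gene Sftpc or the club cell secretoglobin gene Scgb1a1. Scgb1a1 was the brightest gene in 18 of 18 arrays and Sftpc ranked 6 or higher in each, and at such ranks quantile normalization leaves few values a gene can take. Scgb1a1 had a normalized log2 signal of 13.19 in all arrays but C3H/HeJ controls 1 and 2, where it was 13.01.

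In the differences between strains, strain goes together with time since exposure, which was 12 to 14 weeks in C3H/HeJ against 20 to 22 in C57BL/6J and 22 to 24 in A/J, and the fits cannot separate the 2. The test of the difference called 677 genes between C57BL/6J and A/J, with a more positive effect in C57BL/6J for 306 and a less positive one for 371. The inflammatory chemokine Cxcl5 differed by 2.99 ± 0.35 (adjusted p = 0.00034), H2-Ea by 2.98 ± 0.43, the clock genes Arntl and Npas2 by 2.80 ± 0.34 and 2.62 ± 0.46, Sfpq by 2.59 ± 0.31 and Gprin3 by 2.57 ± 0.36. Means in untreated C57BL/6J lung lay below the overall median of 4.98 for H2-Ea (3.76), Cxcl5 (3.06), Arntl (4.56) and Npas2 (3.63). A fall like that in A/J could not be fully seen from these levels. The difference of H2-Ea, at 3.62 in irradiated C57BL/6J lung, restates the A/J change of −3.13. Arntl and Npas2 were higher in irradiated C57BL/6J lung, at 5.29 and 4.19, so their differences do not rest on a hidden fall. In A/J they went from 7.03 to 4.96 and from 5.53 to 3.47. Time of day at sacrifice is not in the labels, so the differences of clock genes cannot be credited to irradiation. The irradiated A/J arrays in this comparison were those with the low 5' to 3' actin ratio of 0.497. On the other side stood Krt4 (−8.81 ± 2.23), Lce1h (−4.94 ± 1.31), Lce3c (−4.75 ± 1.20), Dbp (−4.70 ± 0.29), Fam25c (−4.44 ± 1.13) and Krt78 (−4.05 ± 0.79). All of these but Dbp had untreated A/J means between 3.55 and 4.15, with the same limit for a fall like that in C57BL/6J. Of these last 6, only Dbp was still called without the 3 arrays high in squamous keratins, where 87 genes passed in all and Npas2 did not (2.15 ± 0.49). The other 5 shrank there to −2.25 ± 0.92 (Krt4), −1.50 ± 0.88 (Lce1h), −1.20 ± 0.50 (Lce3c), −1.40 ± 0.55 (Fam25c) and −2.35 ± 0.81 (Krt78). The split without scaling was 27 and 224, and after median centring 181 and 767. Without A/J control 1 the count was 423, without A/J control 2 it was 350, without C57BL/6J irradiated 2 it was 438 and without C57BL/6J control 1 it was 383. Krt4 lost its call without any of 8 of the 12 arrays (−11.21 to −7.05), Lce1h without any of 10 (−6.11 to −3.84), Lce3c without any of 9 (−6.08 to −3.86) and Fam25c without any of 8 (−5.40 to −3.33), each time including every A/J control and C57BL/6J controls 1 and 3.

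Matrix and mast cell genes had the smaller mean effect in C57BL/6J, where the single irradiated arrays differed. Arrays 1, 2 and 3 of that group had signals of 8.617, 8.112 and 7.353 for Col1a1 and 5.821, 4.434 and 3.822 for Mcpt4. Col18a1 (6.615, 7.25 and 6.964) and Cma1 (5.664, 5.804 and 5.068) were not highest in array 1. Collagen and matrix genes were less positive in C57BL/6J than in A/J in 12 of 38 cases and more positive in 1 (20 and 2 adjusted over the list alone, adjusted p = 4.07e-06, adjusted p = 0.158 with an estimated correlation), with Col18a1 at −1.73 ± 0.27 and Col1a1 at −1.73 ± 0.32. Without the 3 arrays high in squamous keratins the Col1a1 difference was −1.65 ± 0.44 and did not pass (adjusted p = 0.101). Mast cell genes were less positive in 5 of 11 cases (7 adjusted over the list alone, adjusted p = 0.000102, adjusted p = 0.205 with an estimated correlation), with Cma1 at −2.62 ± 0.42. Clock genes were less positive in 9 of 17 cases and more positive in 4 (10 and 4 adjusted over the list alone, adjusted p = 5.97e-05, adjusted p = 0.0913 with an estimated correlation). The mean of Dbp was 5.46 in untreated A/J and 9.76 in untreated C57BL/6J lung, against 9.0 and 8.60 in irradiated lung. Genes of B and plasma cells were more positive in C57BL/6J in 5 of 16 cases (9 adjusted over the list alone, adjusted p = 1.97e-08, adjusted p = 0.158 with an estimated correlation), with the B cell surface gene Ms4a1 at 2.33 ± 0.44. In A/J that list did not pass (adjusted p = 0.342), with 3 members higher and 5 lower (3 and 5 adjusted over the list alone). Ms4a1 signals in A/J were 7.921, 8.359 and 7.91 untreated and 6.577, 5.911 and 5.923 irradiated. In C57BL/6J they were 6.412, 7.587 and 6.984 untreated and 7.392, 7.722 and 7.094 irradiated. The antibody gene Ighg3 was called higher in both strains. T and NK cell genes were more positive in C57BL/6J in 3 of 22 cases (5 adjusted over the list alone, adjusted p = 6.35e-07, adjusted p = 0.158 with an estimated correlation), with Cd3d at 1.28 ± 0.30. The Ms4a1 and Cd3d calls were lost without the 3 arrays (1.64 ± 0.51 and 0.75 ± 0.29), and Cd3d also without scaling.

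Between C57BL/6J and C3H/HeJ 199 genes differed in effect, 74 more positive in C57BL/6J and 125 less positive. The antibody genes Ighm (2.77 ± 0.52) and Igkv6-20 (2.35 ± 0.56), the retinoic acid hydroxylase Cyp26b1 (2.58 ± 0.59), Acaa1b (2.48 ± 0.49), 1600014C23Rik (2.21 ± 0.47) and Arntl (2.14 ± 0.34) were the 6 highest. Il6 (−3.80 ± 0.59, adjusted p = 0.00618), Timp1 (−3.23 ± 0.50), Tpsb2 (−2.95 ± 0.49), Tpsab1 (−2.92 ± 0.48), the eosinophil chemokine Ccl24 (−2.92 ± 0.54) and Chl1 (−2.83 ± 0.50) were the 6 lowest. In untreated C57BL/6J lung 1600014C23Rik (4.23) and Arntl (4.56) had means below the overall median of 4.98, from which a fall like that in C3H/HeJ could not be fully seen. Arntl was higher in irradiated C57BL/6J lung, at 5.29, so its difference does not rest on a hidden fall. Chemokines and cytokines were less positive in C57BL/6J in 6 of 35 cases (15 adjusted over the list alone, adjusted p = 8.55e-08, adjusted p = 0.0879 with an estimated correlation), cell cycle genes in 3 of 31 (18 adjusted over the list alone, adjusted p = 7.97e-11, adjusted p = 0.101 with an estimated correlation) and neutrophil genes in 1 of 17 (5 adjusted over the list alone, adjusted p = 1.53e-05, adjusted p = 0.0879 with an estimated correlation). The split without scaling was 9 and 210, and after median centring 29 and 209. Without the 3 arrays high in squamous keratins 18 genes differed, and of the 12 genes named here only Il6, Timp1 and Cyp26b1 were still called. Of the other 9, Ighm (1.78 ± 0.46) shrank by more than 1.5 times, and the rest lay within 1.5 times of their log2 values over all arrays, among them Tpsb2 (−2.85 ± 0.58), Acaa1b (2.63 ± 0.62) and Igkv6-20 (1.68 ± 0.67).

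Leaving out 1 array moved this count by more than 1.5 times for 8 of the 12 arrays. It was 371 without C57BL/6J irradiated 1, 114 and 101 without irradiated 2 and 3, 94 without control 1, 104 and 82 without C3H/HeJ irradiated 1 and 2, 90 and 122 without C3H/HeJ control 1 and 3. Cyp26b1 lost its call without any of 9 arrays (2.11 to 2.96), Igkv6-20 without any of 8 (2.02 to 2.69) and 1600014C23Rik without any of 7 (1.96 to 2.40). Acaa1b lost it without C3H/HeJ irradiated 2 or control 1 (2.18 to 3.07).

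Between C3H/HeJ and A/J 132 genes differed in effect, 69 more positive in C3H/HeJ and 63 less positive. Cxcl5 differed by 3.70 ± 0.35 (adjusted p = 0.000124), H2-Ea by 2.66 ± 0.43, the interferon-inducible Ifi204 by 2.42 ± 0.33, Med18 by 2.35 ± 0.50, Saa3 by 2.35 ± 0.47 and the monocyte chemokine receptor Ccr2 by 2.19 ± 0.38. The irradiated A/J arrays with the low 5' to 3' actin ratio of 0.497 enter this comparison too. The lowest were Dbp (−3.00 ± 0.29), 1600014C23Rik (−2.70 ± 0.47), the endothelial gene Vwf (−1.86 ± 0.24), C6 (−1.83 ± 0.32), Bex1 (−1.74 ± 0.37) and Rbpjl (−1.72 ± 0.37). Untreated means lay below the overall median of 4.98 for Cxcl5 (3.54) and Ifi204 (3.91) in C3H/HeJ and for 1600014C23Rik (3.37) in A/J, from which a fall like that in the other strain could not be fully seen. Genes of dendritic cells and MHC class II were more positive in C3H/HeJ in 2 of 19 cases (14 adjusted over the list alone, adjusted p = 2.61e-12, adjusted p = 0.0263 with an estimated correlation) and neutrophil genes in 0 of 17 (4 adjusted over the list alone, adjusted p = 4.43e-06, adjusted p = 0.042 with an estimated correlation). Cell cycle genes were more positive in 1 of 31 (15 adjusted over the list alone, adjusted p = 4.42e-14, adjusted p = 0.062 with an estimated correlation). The split without scaling was 25 and 11, and after median centring 45 and 25. Without 1 array the count was 61, 38 and 68 (A/J controls 1, 2 and 3), 52 and 73 (C3H/HeJ controls 1 and 2), 55 and 33 (C3H/HeJ irradiated 1 and 2) and 199 (C3H/HeJ irradiated 3, the array between the strains at strain markers). The calls of Vwf, C6, Bex1 and Rbpjl were lost without scaling, and those of Ccr2 and C6 without C3H/HeJ irradiated 2 (1.97 to 2.48 and −2.06 to −1.60 without 1 array). Med18 lost its call without any of 7 of the 12 arrays (2.09 to 2.73), Saa3 and Bex1 without any of 9 (2.18 to 2.48 and −1.98 to −1.53) and Rbpjl without any of 10 (−2.11 to −1.47).

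Untreated lungs of the strains differed in the signals of many genes. Sequence variants of a strain under a probe can also move such signals, and probe positions were not examined. C57BL/6J and A/J controls differed in 1289, 736 higher and 553 lower in C57BL/6J, with Mndal at 5.05 ± 0.22 (adjusted p = 3.81e-10), the ciliary gene Rpgrip1 at 4.74 ± 0.20, Dbp at 4.30 ± 0.20, Mir1931 at 3.92 ± 0.27 and Sox11 at 3.73 ± 0.27. Lower in C57BL/6J were Gbp2b (−4.30 ± 0.18), Tmem87a (−3.59 ± 0.38), Ifi202b (−3.52 ± 0.23), H2-Ea (−3.35 ± 0.30), which C57BL/6J mice are known to lack, and Baiap2l1 (−2.92 ± 0.09). C57BL/6J and C3H/HeJ controls differed in 1344 genes, 746 higher and 598 lower in C57BL/6J (383 and 64 without scaling, 562 and 250 after median centring). Rpgrip1 (5.20 ± 0.20), the MHC class I gene H2-D1 (4.0 ± 0.67), the squamous gene Sprr3 (3.81 ± 1.10), Mir1931 (3.77 ± 0.27) and Sox11 (3.64 ± 0.27) were the 5 highest, and Gbp2b (−3.65 ± 0.18), Tmem87a (−3.43 ± 0.38), H2-Ea (−3.32 ± 0.30), Baiap2l1 (−2.90 ± 0.09) and Pik3ap1 (−2.75 ± 0.24) the 5 lowest. Without A/J control 2 the first of these counts was 853, and without C3H/HeJ control 1 the second was 891. The first was 384 without scaling (223 higher and 161 lower) and 882 after median centring (493 and 389). Both counts also fell without the 3 arrays high in squamous keratins, which leaves 1 C57BL/6J control. The Sprr3 call rested on the 2 controls high in squamous keratins and was lost without control 1, control 3 or any C3H/HeJ control (3.02 to 5.23), and H2-D1 had another probe set called in the opposite direction.

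C3H/HeJ and A/J controls differed in 558 genes, 290 higher and 268 lower in C3H/HeJ (36 and 215 without scaling, 139 and 214 after median centring). Without A/J control 1, 2 or 3 the count was 365, 337 or 364, and without C3H/HeJ control 1 it was 328. Mndal (5.18 ± 0.22), Tnn (3.28 ± 0.42), Exosc1 (3.26 ± 0.41), Zfp945 (2.86 ± 0.22) and the troponin gene Tnnt1 (2.79 ± 0.25) were the 5 highest, and H2-D1 (−4.21 ± 0.67), Nptx1 (−3.40 ± 0.37), Efhd2 (−3.24 ± 0.37), the MHC class I gene H2-Q5 (−3.08 ± 0.26) and Pdxdc1 (−2.78 ± 0.38) the 5 lowest. H2-D1, Exosc1, Zfp945 and Pdxdc1 each had another probe set called in the opposite direction. Probe sets of H2-D1 reached 4.93 and −6.3 in this comparison, so such values need not reflect amounts of RNA. The Y-linked genes Eif2s3y, Kdm5d and Uty were higher in C3H/HeJ than in A/J controls, by 0.77 ± 0.13, 0.80 ± 0.18 and 1.26 ± 0.26. None of them passed in the effect of irradiation in any strain, and neither did Xist. The Kdm5d call was lost without A/J control 2 or any C3H/HeJ control (0.74 to 0.83), and the Uty call without C3H/HeJ control 1 (1.11 to 1.42). All 3 were lost without scaling, and Kdm5d also after median centring.

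**Figure D3:**
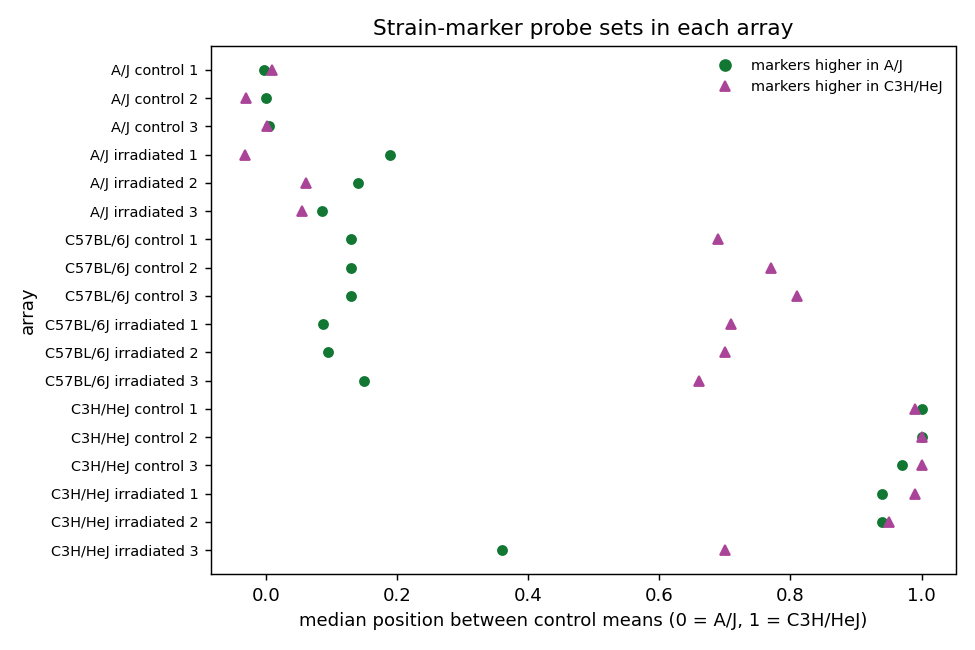
Median position of each of the 18 arrays (vertical axis) between the control means of A/J (0) and C3H/HeJ (1) on the horizontal axis, over 40 probe sets higher in untreated A/J (circles) and 44 higher in untreated C3H/HeJ (triangles). C3H/HeJ irradiated 3 lay at 0.36 and 0.70, while irradiated 1 and 2 of that strain lay between 0.94 and 0.99.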

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

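The splits of the arrays were planned before the data were examined, while the tests of clock phase, strain variants, RNA quality, strain markers and neighbouring tissue were chosen only after the results were seen.

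The change from untreated to irradiated lung differed between strains by the test of the difference itself. Strain goes together with time since exposure there, 12 to 14 weeks in C3H/HeJ against 20 to 22 in C57BL/6J and 22 to 24 in A/J, so these tests cannot separate the 2. Between C57BL/6J and A/J 677 genes and 12 gene lists differed, with Cxcl5 at 2.99, H2-Ea at 2.98, Arntl at 2.80, Npas2 at 2.62, Sfpq at 2.59 and Gprin3 at 2.57. Untreated C57BL/6J means lay below the overall median of 4.98 for H2-Ea (3.76), Cxcl5 (3.06), Arntl (4.56) and Npas2 (3.63), from which a fall like that in A/J could not be fully seen. The difference of H2-Ea therefore only restates the A/J change of −3.13. Arntl and Npas2 were higher in irradiated C57BL/6J lung, at 5.29 and 4.19, so their differences do not rest on a hidden fall. Krt4 stood at −8.81, Lce1h at −4.94, Lce3c at −4.75, Dbp at −4.70, Fam25c at −4.44 and Krt78 at −4.05, and all of these but Dbp had untreated A/J means between 3.55 and 4.15, with the same limit. Between C57BL/6J and C3H/HeJ 199 genes and 24 lists differed, with Ighm at 2.77, Cyp26b1 at 2.58, Acaa1b at 2.48, Igkv6-20 at 2.35, 1600014C23Rik at 2.21 and Arntl at 2.14. An untreated C57BL/6J mean of 4.23 set the same limit for 1600014C23Rik, while Arntl was higher in irradiated than in untreated C57BL/6J lung. Il6 stood at −3.80, Timp1 at −3.23, Tpsb2 at −2.95, Tpsab1 at −2.92, Ccl24 at −2.92 and Chl1 at −2.83. Between C3H/HeJ and A/J 132 genes and 14 lists differed, with Cxcl5 at 3.70, H2-Ea at 2.66, Ifi204 at 2.42, Med18 at 2.35, Saa3 at 2.35 and Ccr2 at 2.19. Dbp stood at −3.00, 1600014C23Rik at −2.70, Vwf at −1.86, C6 at −1.83, Bex1 at −1.74 and Rbpjl at −1.72. The limit holds there for Cxcl5 (3.54) and Ifi204 (3.91) in untreated C3H/HeJ and 1600014C23Rik (3.37) in untreated A/J lung. With an estimated correlation 0, 0 and 2 of these list differences were called.

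For the difference between C57BL/6J and A/J, 3 of 100 splits of the arrays gave as many genes as the real 677, a share under 0.05, with 897 as the highest other split drawn. For C57BL/6J against C3H/HeJ 6 of 100 splits gave as many as the real 199, with 2891 as the highest other, and for C3H/HeJ against A/J 5 of 100 gave as many as the real 132, with 1391 as the highest other, so chance cannot be excluded there. Splits that call several times the real count point to a structure of the samples. Exchanging the controls of the 2 strains turns the contrast into the strain difference over both treatments, and that split gave 2782, 2891 and 1391 genes. It was among the splits drawn for the other 2 differences and not for C57BL/6J against A/J. Splits that mix the 2 strains within a group also put the strain difference into the spread, which lowers their counts. The share for the 677 genes therefore cannot exclude chance either. The 6 arrays of each other comparison make 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) gave as many genes in each. The other splits of these arrays mix the 2 compared groups, which puts their difference into the spread and lowers the counts. Low counts in those splits therefore add no support for the real counts. The real counts and the highest of the other splits were 2986 and 1 in A/J, 664 and 0 in C57BL/6J, 2915 and 0 in C3H/HeJ, 1289 and 0 for C57BL/6J against A/J controls, 1344 and 0 for C57BL/6J against C3H/HeJ controls, and 558 and 2 for C3H/HeJ against A/J controls.

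Clock genes differed between untreated lungs. Of 17 measured, 15 were called between C57BL/6J and A/J controls and 15 of these lay in phase order, with genes that cycle with Dbp higher in C57BL/6J and their antiphase partners Arntl, Clock, Npas2 and Nfil3 lower. A strain variant would leave the same difference in irradiated lung, where the median ratio of the irradiated to the control difference was −0.1 (range −0.509 to 0.618), and the 5' to 3' actin ratio of the 2 control groups differed by only −0.026, so the tables argue against both as the whole source. A different time of day at sacrifice, which the labels do not give, may account for the order, and a strain difference in clock phase that irradiation or moribund state removes stays open and untested.

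C3H/HeJ irradiated array 3 lay between C3H/HeJ and A/J at 84 strain-marker probe sets. Some of these name the same gene, such as H2-D1 and Pdxdc1, and the clock gene Dbp is among them. They are therefore not 84 independent markers. The median position of all 84 was 0.58 on a scale from 0 (A/J controls) to 1 (C3H/HeJ controls). A/J arrays lay at 0.087 or lower, which argues against a whole A/J sample. At markers between A/J (0) and C57BL/6J (1) controls this array lay at 0.19. The C57BL/6J arrays lay at 0.97 to 1 there, which argues against a whole C57BL/6J sample. A whole sample of a strain outside this study was not tested. The 40 markers with no response in the other arrays lay at 0.56, which argues against a response of this mouse. Markers higher in C3H/HeJ lay at 0.70 and those higher in A/J at 0.36, where an equal mix of both controls would give 0.71 and 0.30. RNA or alleles of both strains in this sample are therefore a candidate explanation. No test here tells mixed RNA from a mouse that carries alleles of both strains.

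Squamous keratin genes were high in C57BL/6J control arrays 1 and 3 and A/J irradiated array 3, with list means of 7.95, 7.88 and 7.44 against at most 4.97 elsewhere. Because 2 of these 3 arrays were untreated, the tables argue against a response to irradiation. The 3 arrays with the highest skeletal muscle signals were the same 3, and the mouse oesophagus holds both squamous lining and skeletal muscle, so oesophagus carried over with the lung is a candidate source, with Krt4 at 11.5, 11.7 and 10.9 and Krt13 at 10.6, 10.7 and 10.3. Skin or another squamous tissue with attached muscle was not tested and stays open.

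The 5' to 3' actin ratio, read from control probe sets outside the gene tests, was 0.497 in irradiated A/J lung and 0.735 in its controls. The Gapdh ratio was 0.734 ± 0.389 (SD, n = 3) and 1.24 ± 0.0873, with irradiated array 1 at 0.294, and these arrays enter the differences against A/J. Low ratios go together with irradiation in A/J, so no test here separates RNA quality from irradiation in that strain.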

How the results depend on the processing

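Leaving out the 3 arrays high in squamous keratins was chosen after the data were seen, and the other alternatives were planned. The count of genes called moved by over 1.5 times as follows, and the cause was not tested unless given. Without scaling it was 220 for C57BL/6J, 251 for the difference of C57BL/6J and A/J, 36 for that of C3H/HeJ and A/J, and 384, 447 and 251 for the controls of C57BL/6J and A/J, C57BL/6J and C3H/HeJ, and C3H/HeJ and A/J. Median centring gave 4698 for A/J, 342 for C57BL/6J, 70 for the difference of C3H/HeJ and A/J, and 812 and 353 for the controls of C57BL/6J and C3H/HeJ and of C3H/HeJ and A/J. With no filter, which tests more genes, C57BL/6J had 408 and the differences 440, 99 and 47. With all probe sets as units the counts are of 25746 probe sets and not of 12412 genes, so they are not directly comparable. A/J then had 6480, C3H/HeJ 4732, the differences of C57BL/6J and C3H/HeJ from A/J 2134 and 353, and the controls 2603, 2604 and 1125. A fit on only the groups compared gave 79 for C57BL/6J and 446 for the difference of C57BL/6J and A/J, and a variance trend with a robust prior gave 247 for that of C3H/HeJ and A/J. Without the 3 arrays, which leaves fewer samples, C57BL/6J had 32, the differences 87, 18 and 65, and the C57BL/6J control comparisons 404 and 420.

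Leaving out 1 array gave 2100 to 2705 genes in A/J, 219 to 731 in C57BL/6J and 2140 to 2403 in C3H/HeJ. The differences ranged from 350 to 714, 82 to 371 and 33 to 199, and the controls from 853 to 1146, 891 to 1082 and 328 to 451. The lowest control counts were without A/J control 2, C3H/HeJ control 1 and C3H/HeJ control 1.

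With an estimated correlation 0 lists were called in A/J, 2 in C57BL/6J, 9 in C3H/HeJ and 0, 0 and 2 for the differences. Without scaling, Clic5, Akap5 and Idi1 turned to 0.07, 0.20 and 0.09 in A/J, and Car2 and Pecam1 to 0.21 and 0.19 in C3H/HeJ, below the median shift of all genes. No other alternative turned a named gene. The named values counted next include genes fixed in advance that had no call to lose, so the shares of lost calls read too low. Of 637 named values, 160 lost their call without scaling, the 5 that turned included, 66 after median centring, 42 with an offset of 1, 97 with no filter, 38 with all probe sets, 127 with only the groups compared and 13 with a variance trend. Of 575 values with a stricter filter 0 lost their call, of 479 without the 3 arrays 203 did, and of 4992 with 1 array left out 876 did.

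Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.084 to 0.096. With the replicate block C57BL/6J had 324 genes, the differences 347, 79 and 39, and 106 of the 637 named values lost their call. Dim genes are limited by signal over background, since all values below the offset of 7 are compressed.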

Other observations

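The tests of clock phase and of probe set pairs were chosen only after the results were seen, and the gene lists were fixed before the data were examined.

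Clock genes differed between irradiated and untreated lung in A/J and C3H/HeJ. In A/J 11 of 17 rose and 3 fell (11 and 3 adjusted over the list alone, adjusted p = 0.000488, adjusted p = 0.0706 with an estimated correlation), with Per2 at 2.84 ± 0.12 and Npas2 at −2.07 ± 0.33. In C3H/HeJ 8 rose and 3 fell (9 and 3 adjusted over the list alone, adjusted p = 0.00761, adjusted p = 0.0832 with an estimated correlation), with Per2 at 1.35 ± 0.12 and Arntl at −1.41 ± 0.24. In C57BL/6J the list did not pass (adjusted p = 0.657), with 2 higher and 2 lower (3 and 2 adjusted over the list alone). The irradiated groups lay close together for Dbp, at means of 9.0 in A/J, 8.60 in C57BL/6J and 8.41 in C3H/HeJ, while the untreated means were 5.46, 9.76 and 7.87. Time of day at sacrifice is not in the labels and may differ between the groups, so these changes cannot be credited to irradiation.

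Genes of TGF-beta and fibrogenic signals rose in 11 of 30 cases in C3H/HeJ and fell in 5 (15 and 6 adjusted over the list alone, adjusted p = 0.0113, adjusted p = 0.162 with an estimated correlation). The growth factor Igf1 rose by 2.39 ± 0.27 and the activin subunit Inhba by 2.28 ± 0.41. In A/J the list did not pass (adjusted p = 0.346, and 0.00173 as adjusted p of fry), though 9 of its members rose and 4 fell (9 and 4 adjusted over the list alone), with Igf1 at 1.93 ± 0.27. It did not pass in C57BL/6J (adjusted p = 0.0871), with 2 higher and 2 lower (7 and 3 adjusted over the list alone). Genes of lipid and lysosomal handling passed in C3H/HeJ (10 of 22 rose and 2 fell, 13 and 2 adjusted over the list alone, adjusted p = 0.0342, adjusted p = 0.49 with an estimated correlation), and in A/J, where 11 rose and 2 fell (13 and 3 adjusted over the list alone), the list did not pass (adjusted p = 0.114, and 0.0363 without scaling). They also passed in C57BL/6J (4 of 22 rose and 1 fell, 8 and 2 adjusted over the list alone, adjusted p = 0.000388, adjusted p = 0.293 with an estimated correlation), with Apoe, a lipid carrier of macrophages, at 1.14 ± 0.24. The Apoe call was lost without irradiated array 1 or control array 1 of that strain (0.91 to 1.34 without 1 array) and without the 3 arrays high in squamous keratins (1.04 ± 0.32). The differences of this list between strains did not pass (adjusted p of 0.448 for C57BL/6J against A/J, 0.332 for C57BL/6J against C3H/HeJ and 0.747 for C3H/HeJ against A/J). The fatty acid transporter gene Cd36 fell by 1.49 ± 0.11 in A/J and 1.08 ± 0.11 in C3H/HeJ.

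Pairs of probe sets for 1 gene, over 1775 genes with a mean log2 signal above 7, differed in their fold change by a median of 0.23 in A/J, 0.0982 in C57BL/6J and 0.161 in C3H/HeJ.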
